A study of Citrus unshiu with 2 samples.

How the data were processed

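The material was stem tissue from shoots of satsuma mandarin (Citrus unshiu), a seedless citrus tree, kept under cover with the roots confined. Per the labels' protocols, 20 trees each were set aside for normal watering and for water deficit, in which the soil was left to dry to a set moisture of about 15%. Tissue labelled Day 75 was used for both groups, within an experiment of 5 months that ran until flower buds appeared. Each group has 1 RNA-seq library, named here the control library and the light drought library. The labels do not say how many trees went into each library.

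Per the labels' protocols, RNA was taken with TRIzol and 2 µg of total RNA entered a stranded mRNA kit. Trimmomatic 0.36 is named in the submitters' processing notes. The aligner, the counting tool, the genome build and whether strand was used in counting are not given in the sources used here.

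Expression values are RPKM (reads scaled to exon length and to library total), deposited by the authors for 23159 genes and both libraries. Gene length, per the file headers, equalled the merged exon length of all 23159 gene models. RPKM multiplied by length gave whole reads, within 0.01 read, for 100% of the values above 0. The recovered totals were 32856618 reads in genes for the control and 31760704 for light drought, and RPKM was relative to these totals. At the median gene length of 1692 bases, a floor of 3 reads corresponds to an RPKM of 0.0540 in the control and 0.0558 in light drought.

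A second table deposited by the authors lists 2568 genes with descriptions, and its name calls them all differential genes. For 820 of them it gives a p-value, a false discovery rate and a log2 fold change of light drought against control, deposited by the authors. The other 1748 have no statistics for this comparison, and on what ground they count as differential is not given in the sources used here. Kept genes among the 1748 had log2 ratios with an SD of 0.51, against 0.26 for kept genes outside the 2568. Gene names came from this table, so a gene outside the 2568 could not enter a gene list. A reference table of locus tags matched 0 of the 23159 identifiers and was not used.

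The main measure was log2((light drought + 0.5)/(control + 0.5)) on RPKM, which understates the change of low genes. Genes with RPKM of at least 1 in either library were kept, and a gene counted as higher or lower at 2-fold or more on this scale. With 1 library per group no p-value was computed for the conditions. For single genes an exact 95% conditional (Clopper-Pearson) interval of the log2 RPKM ratio was computed from the recovered reads, without the pseudocount, so for low genes it can lie beyond the main log2 ratio. Reads without molecular identifiers are not independent molecules, and these intervals and floors cover counting error only, not differences between trees.

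Text patterns for 36 gene lists were fixed before the data were examined and matched to gene descriptions. The median log2 ratio of each list with at least 5 kept members was placed among 10000 random lists of the same size, drawn from 1235 named kept genes and matched in 20 bins of mean expression. This percentile describes these libraries and is not a test of the conditions. A list outside the central 95% of random lists is called below or above the random range.

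Most genes were named by a rule fixed before the data were examined. It took the 8 largest rises and 8 largest falls among named genes with a mean RPKM of at least 5. It added up to 3 members of each flowering or methylation list and up to 2 of every other list, by absolute log2 ratio among kept members, of which the text may name fewer. Homologues of FT, TFL1, SOC1, AP1, LFY, SVP, FLC and FD and of DNA methyltransferases and demethylases were named whatever their value. Other genes, among them CONSTANS-LIKE 4, CONSTANS-LIKE 14, APETALA 2 and Lea5, were named outside this rule, after the data were seen.

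On simulated libraries with 200 changed genes, the 2-fold rule recovered 84.0% of genes changed 2.5-fold and 100% of those changed 4-fold under counting error alone, with 4 unchanged genes counted among 15451. With a dispersion of 0.04 between libraries, it recovered 70.0% and 95.0%, and 195 unchanged genes were counted among 15495. The alternatives were other pseudocounts, filters, thresholds and scalings. Alternatives chosen after seeing the data were fixed-dispersion tests of the recovered reads, a stricter false discovery rate and lists without chance text matches. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.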

Results

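Expression was compared between stems of normally watered mandarin trees and stems of trees under light drought, to examine flowering-related and methylation-related genes. The control library held 32856618 reads in genes and the light drought library 31760704. RPKM reached 1 in 15315 and 15129 of the 23159 genes, and 1727 and 2087 genes were at 0. The most abundant gene, Cs5g27060, a single-exon gene of 408 bases at 29761632 to 29762039 on chromosome 5, carries no name in the files. It took 8.22% of control reads and 8.90% of light drought reads. Each group had 1 library, so no difference below has a replicate check.

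Among named genes with a mean RPKM of at least 5, the largest falls in light drought stems included a C2H2-type zinc finger gene (Cs7g01850), at RPKM 0.643 against 13.1 in the control, and a pectate lyase (Cs5g06600), a pectin-cutting enzyme, at 1.45 against 12.4. An ACC oxidase (Cs2g02500), which makes ethylene, was at 1.50 against 10.7. SHI RELATED SEQUENCE 5 (Cs3g25570), a regulator of organ development, was at 4.23 against 25.7. The largest rises of these genes included a basic glucan endo-1,3-beta-glucosidase (orange1.1t00634), at 116 against 26.6, and early light-induced protein 1 (Cs9g07670), a chloroplast protein of light stress, at 1118 against 317.

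The fall of Cs7g01850 (chromosome 7, 556793 to 559126) was -3.57 on the log2 scale. Non-specific lipid-transfer protein 1 (Cs6g09950) followed at -2.97, with a counting interval of the RPKM ratio from -3.71 to -2.88. The other falls among the 8 largest of these genes included organ-specific protein S2 (Cs8g06620, -2.51), ABC transporter G family member 22 (Cs6g13330, -2.29) and the transcription factor bHLH75 (Cs6g18610, -2.24). The rise of orange1.1t00634 was 2.11, with a counting interval from 2.03 to 2.22. A class I heat shock protein (Cs2g24040) rose by 1.82, from RPKM 10.8 to 39.7, and an acid invertase (Cs5g09220), which splits sucrose, by 1.65, from 39.4 to 124. Non-specific lipid-transfer protein 4 (orange1.1t01623, 1.69), the cinnamoyl-CoA reductase-like SNL6 (Cs4g02410, 1.59), a GDSL esterase/lipase (Cs4g10140, 1.56) and CASP-like protein 1D1 (Cs9g04890, 1.49) completed the 8 largest rises of these genes.

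Of 15654 genes kept, 470 differed at least 2-fold, 138 higher and 332 lower in light drought. These counts depend on the settings, with 292, 88 and 204 at a pseudocount of 1, 208 higher at one of 0.1 and 513 lower after rescaling to equal sums. In the list counts below, genes that fell or rose did so by at least 2-fold. The background for those counts is the 1235 named kept genes, of which 187 fell and 72 rose by the same rule. Their median log2 ratio was -0.25, against 0.0024 for all 15654 kept genes. The counting interval excluded no change for 467 of the 470, which selecting genes at least 2-fold apart from the same reads makes likely. Exon bases were shared with another gene model for 13 of the 470, and whether strand was used to assign the reads of such models is not known. In simulations, 4 unchanged genes passed the same rule under counting error alone, but 195 did with a dispersion of 0.04 between libraries. The real dispersion cannot be estimated from 1 library per group, so 195 is not an upper limit.

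**Figure D1:**
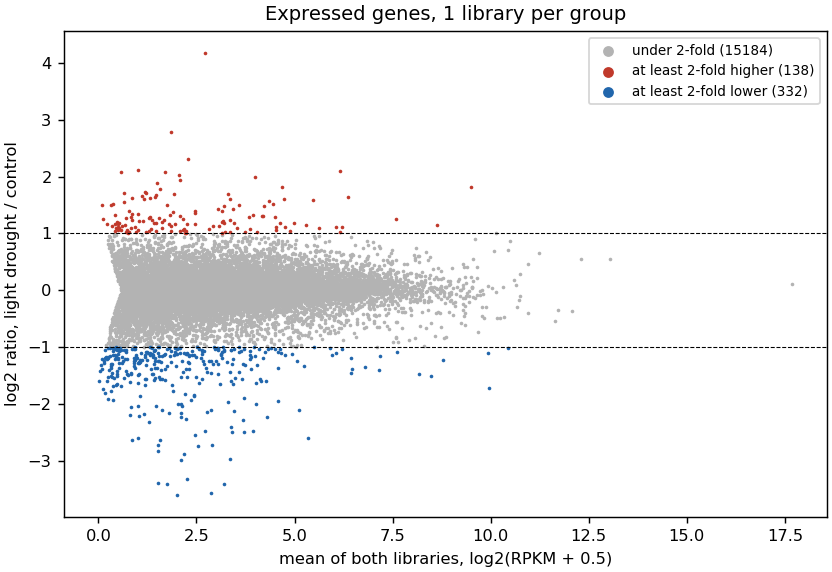
Each point is 1 of 15654 kept genes, with the mean of both libraries as log2(RPKM + 0.5) on the horizontal axis and the log2 ratio of light drought to control on the vertical axis. Dashed lines mark 2-fold, passed by 138 genes above and 332 below.

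Both floral organ MADS-box genes matched by the fixed list fell in light drought stems, and the FT and AP1 relatives lay between the control level and a 2-fold fall. DEFICIENS (Cs1g24860), a MADS-box gene of petal and stamen identity, was at RPKM 0.593 against 2.96 in the control (log2 ratio -1.66, counting interval of the RPKM ratio -2.94 to -1.75). AGL6 (orange1.1t00275), another floral MADS-box gene, was at 0.0628 against 1.00, from 2 reads in light drought (counting interval -7.10 to -2.03). The FT homologue HEADING DATE 3A (Cs6g05520, chromosome 6, 7014700 to 7015580), of the family of the mobile flowering signal, stood at 3.35 against 6.69. Its log2 ratio of -0.90 was under 2-fold, with a counting interval of -1.68 to -0.35 from 30 light drought reads. CAULIFLOWER A (Cs7g11810), described in the files as a truncated factor and related to AP1, stood at 20.8 against 38.7 (-0.88). The flowering lists did not match APETALA 2 (Cs6g04120), described as a floral homeotic protein, which stood at 5.03 against 11.5 (-1.12).

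Among 7 photoperiod and clock genes, 3 fell at least 2-fold on the scale with the pseudocount and none rose that much on it. The falls were CONSTANS-LIKE 11 (Cs8g17670, -1.53), the pseudo-response regulator APRR3 (Cs7g27910, -1.15) and ELF4-LIKE 4 (Cs1g17640, -1.03). The other 4 were CONSTANS-LIKE genes with ratios above 0, up to 0.88, and the authors' deposited table calls CONSTANS-LIKE 4 (Cs2g07080) higher with a log2 fold change of 1.13, and CONSTANS-LIKE 14 (Cs2g14170) too. The photoperiod median of 0.56 lay inside the random range of -0.99 to 0.66. The age pathway gene SPL13A (orange1.1t02597) fell by 1.03. A pair of genes described as VRN1 (vernalization) went apart, Cs5g28670 at 1.20 and Cs5g28570 at -1.08. UPSTREAM OF FLC (Cs1g01250), matched by its name and not a homologue of FLC, fell by 1.28. TFL1, SOC1, LFY, SVP, FLC and FD homologues were not named in the descriptions used here.

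None of the few methylation genes named in the descriptions passed 2-fold. Those were 1 DNA methyltransferase, 1 gene of the RNA-directed methylation list, 2 histone methylation genes and 1 gene of the methyl donor cycle. Methylation genes outside the 2568 described genes were not assessed. DNA (cytosine-5)-methyltransferase 1B (Cs3g03480, chromosome 3, 3730568 to 3738432), of the enzymes that copy DNA methylation, stood at RPKM 0.312 against 0.367, under the expression minimum (counting interval -0.86 to 0.39). DDM1-like (Cs1g24000), of the chromatin remodellers needed for DNA methylation, stood at 3.54 against 6.75 (-0.84, interval -1.11 to -0.75). The histone methyltransferase ATXR4 (Cs6g12910) had a log2 ratio of 0.19 and homocysteine S-methyltransferase 3 (Cs9g07420), of the methyl donor cycle, 0.91. A second gene shares the description record of ATXR4, so reads may have been split between copies. No DNA demethylase was named in the descriptions used here.

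**Figure D2:**
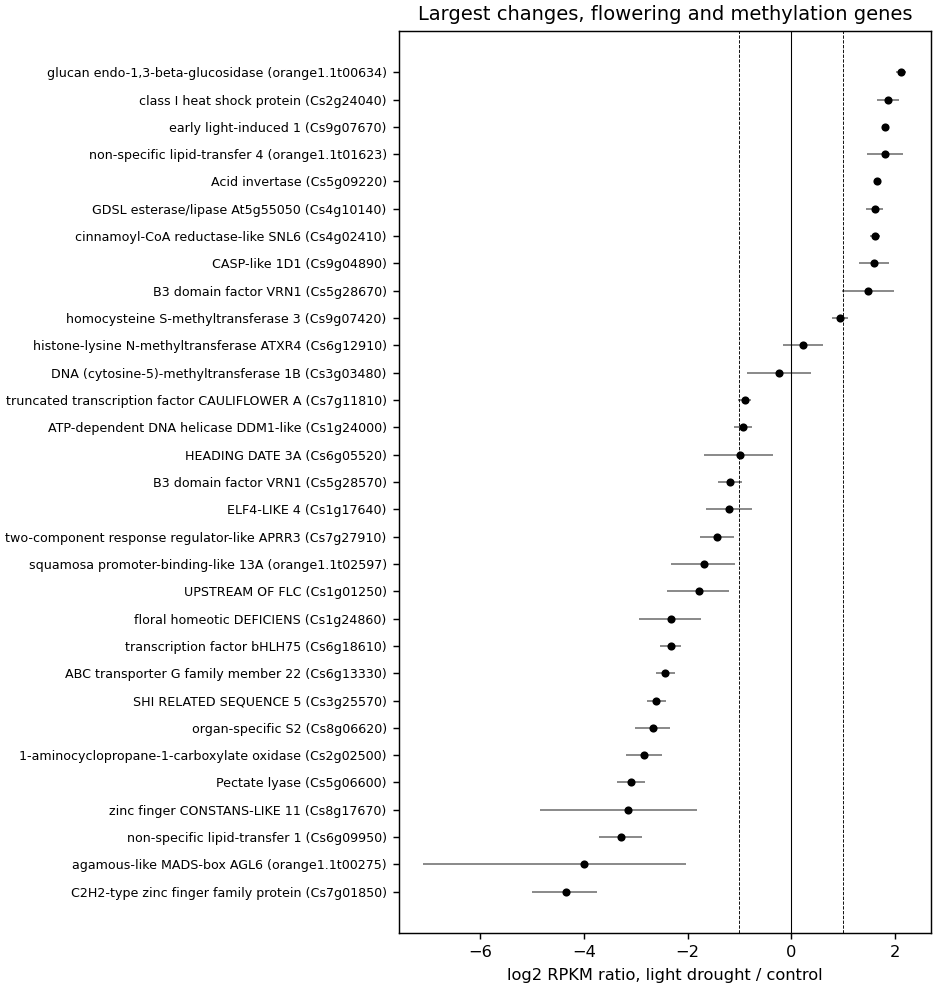
Points are log2 RPKM ratios of light drought to control, without a pseudocount, for the largest rises and falls at a mean RPKM of at least 5 and the flowering and methylation genes, and bars are 95% counting intervals from 1 library per group. Dashed lines mark 2-fold, and the bars of HEADING DATE 3A (-1.68 to -0.35) cross it.

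Cell wall loosening genes were lower as a group under every setting run. The shoot meristem list lay below its random range wherever it kept at least 5 members. The cell division list did not in the main setting. All 24 kept cell wall loosening genes had ratios below 0 and 9 fell at least 2-fold, led by the pectate lyase Cs5g06600 (-2.72) and expansin-A1 (Cs7g03630, -1.93, 2 reads in light drought). The list median of -0.81 lay below the random range of -0.64 to 0.32. Among 8 genes matched to the shoot meristem list 4 fell, with YABBY 5 (Cs4g18050, -1.49) and LOB domain-containing protein 4 (Cs2g10630, -1.23) first. The descriptions of these leading genes do not name the meristem, and a text match does not make each of the 8 a meristem gene. The list median of -1.03 lay below the random range of -0.97 to 0.52. With a minimum RPKM of 5 the list kept 3 members, too few to be placed. Among 7 cell division genes, 2 D-type cyclins fell, cyclin-D3-1 (Cs3g23120, -1.42) and cyclin-D2-2 (Cs1g21610, -1.24), and the median of -0.88 lay inside the random range of -0.93 to 0.45, though below it without the expression minimum.

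Photosynthesis genes were higher as a group, by less than 2-fold each in most cases. Of 28 members 27 had ratios above 0, and the median of 0.58 lay above the random range of -0.53 to 0.43. Photosystem I chlorophyll a/b-binding protein 6 (Cs4g07150) rose from RPKM 0.713 to 2.11, and the exception, a Rubisco small chain (Cs4g03580), fell by 1.64, from 23.9 to 7.30. Among 15 starch and sucrose genes 5 fell and 2 rose, and the median of -0.77 lay below the random range of -0.68 to 0.45, a call lost without the expression minimum. The falls were led by a galactinol-sucrose galactosyltransferase (Cs4g07840, -2.01) and the rises by the acid invertase Cs5g09220. The median of 15 lignin and secondary wall genes was 0.30, inside the random range, with 4 rises, among them SNL6, and 1 fall, fasciclin-like arabinogalactan protein 17 (Cs7g23810, -1.36).

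Genes matched to ethylene by their descriptions were mostly lower, and single abscisic acid genes fell. Of the 12, 11 are described as ethylene-responsive transcription factors, a family name that does not make each an ethylene gene, and 1 as an ethylene synthesis enzyme. At least 2-fold falls were seen for 7, and the median of -1.18 lay below the random range of -0.87 to 0.45. With a minimum RPKM of 5 the list kept fewer than 5 members and was not placed. The leading members were the ACC oxidase Cs2g02500 (-2.49) and ANT (Cs1g21310, -2.04), known as a regulator of organ growth. Without ANT and the fatty acid regulator WRI1, the median of 10 members was -1.03, still below its range. ABSCISIC ACID-INSENSITIVE 5 (Cs6g14970, -2.31), a transcription factor of abscisic acid response, and the kinase SAPK2 (Cs1g19910, -1.09) fell among 5 signalling genes. An abscisic acid 8'-hydroxylase (Cs6g19380), which breaks the hormone down, fell by 1.24. Snakin-2 (Cs5g04980, -2.11) and snakin-1 (Cs8g04550, -1.60) were among 3 falls in 4 gibberellin-related genes, a list with 5 or more members, and then below its random range, only without the expression minimum or with rescaling to equal sums.

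Late embryogenesis abundant protein D-29 (Cs1g24210) fell by 2.17 and an 11 kDa member (orange1.1t02242) by 1.56. They belong to 7 genes matched by description text to the dehydrin and LEA list, with a median of -0.83. A text match does not make each of the 7 such a protein. Of these, 3 had ratios above 0, among them the most abundant, Lea5 (Cs9g04210), at RPKM 5955 against 4085 (0.54, counting interval 0.52 to 0.56). Aquaporins PIP1-2 (Cs6g07970, -1.78) and NIP5-1 (Cs3g20790, -1.53) fell among 6. Of 31 antioxidant genes 6 fell, led by peroxidase 42 (Cs2g03110, -2.11), and none was 2-fold higher, though 12 had ratios above 0. The medians of the abscisic acid signalling (-0.72), dehydrin, aquaporin (-0.72) and antioxidant (-0.23) lists lay inside their random ranges, though the dehydrin list lay below with a pseudocount of 0.1 or rescaling to equal sums.

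The remaining lists with at least 5 members lay inside their random ranges too. Their medians were -0.36 for 11 heat shock genes, with 2 rises and 2 falls, and -0.32 for 19 jasmonate and salicylate genes, with 1 of each. They were -0.10 for 7 osmolyte genes, where stachyose synthase (orange1.1t01707) rose by 1.24 and the galactosyltransferase Cs4g07840 fell by 2.01, 0.13 for 13 auxin genes and 0.054 for 5 phloem genes. Smaller lists have values only. Cytokinin genes had a median of -0.19 and flavonoid genes 0.11. Of the flavonoid genes, chalcone synthase 2-like (Cs2g14720) was up by 1.14 and an anthocyanidin glucosyltransferase-like gene (Cs2g05350) down by 1.07. Terpene genes had a median of 0.11, cytosolic ribosomal proteins -0.071, the root gene a value of -0.46 and the nuclear psbY gene 0.64. The 3 genes matched to pollen and anther had a median of 0.45. They include a spermidine synthase (Cs4g06030, 0.70), whose description does not name pollen, and a pollen-specific extensin-like gene (Cs1g17860) that fell by 1.13. Named genes come from the table of 2568, so members of a family outside it are not in these counts.

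**Figure D3:**
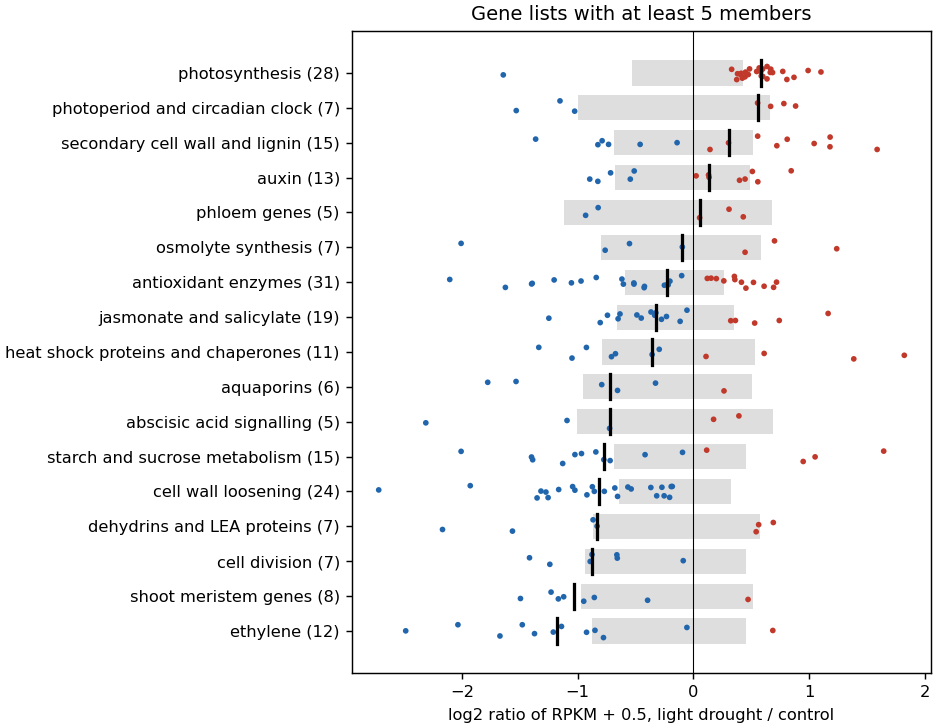
Points are log2 ratios of light drought to control for kept members of each gene list, with the number of members in brackets, black bars are list medians and grey bands the central 95% of medians of 10000 random lists. The photosynthesis median (0.58) lies above its band, and the ethylene (-1.18), shoot meristem (-1.03), cell wall loosening (-0.81) and starch and sucrose (-0.77) medians lie below theirs.

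The authors' deposited table calls 820 genes changed, 238 higher and 582 lower in light drought. The authors' deposited table gives DEFICIENS a log2 fold change of -2.32 and AGL6 one of -3.91, and gives none for HEADING DATE 3A, CAULIFLOWER A or DDM1-like. Of the 470 genes at least 2-fold apart, 426 are among the 820 calls of the authors' deposited table, and 171 of its calls have RPKM under 1 in both libraries. The false discovery rate in the authors' deposited table reaches 0.251, and 716 of its calls have one of at most 0.05. A negative binomial test of the recovered reads with a fixed dispersion of 0.01, chosen after seeing the data, gave p within 0.3 log10 units for 98.5% of the calls in the authors' deposited table. With genes under 1 RPM in both libraries left out, it reached all 820 calls and 3 other genes. Such a test compares these 2 libraries, not the conditions, and at a dispersion of 0.04 or 0.16 the genes at an adjusted value of 0.05 numbered 228 and 12 in place of 716.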

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

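The fixed-dispersion tests, the stricter false discovery rate and the lists without chance text matches were chosen after seeing the data. No paired analysis was possible because each group has 1 library, and leaving out a library was not possible for the same reason. More genes were lower than higher under every setting run. Of the counts in the text (470 changed, 138 higher, 332 lower), a pseudocount of 0.1 moved the higher genes to 208, and a pseudocount of 1 gave 292 changed, 88 higher and 204 lower. A minimum RPKM of 5 gave 227, 68 and 159, from fewer genes. A threshold of 1.5-fold gave 1596, 631 and 965, and one of 4-fold 52, 8 and 44, by construction. Rescaling to equal sums gave 513 lower genes, and the cause was not tested. It raised the values, so that 16563 genes in place of 15654 were kept and the pseudocount weighed less, and it shifted kept genes by -0.042. Lists outside the random range numbered 5, and 3 with a minimum RPKM of 5, where fewer lists keep 5 members. They numbered 6 with a pseudocount of 0.1, where the dehydrin list fell below, 6 without a filter, where cell division and gibberellin did, and 7 with equal sums, where gibberellin and dehydrins did. Cell wall loosening and photosynthesis stayed outside under every setting run. Of the 820 calls, 445 were at least 2-fold on the scale with the pseudocount, 252 had RPKM of at least 5, and a fixed dispersion of 0.16 gave 197. Of 264 medians of single lists under other settings 240 moved by less than their spread, as did 357 of 360 ratios of named genes, and none reversed. Depth limits low genes most, such as expansin-A1 and AGL6 with 2 reads each in light drought.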

Other observations

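The families in the next paragraph and the tests on growth and photosynthesis genes were chosen after their results were seen, as was the count of pairs with no gene model between them, while the other tests on neighbouring genes were set before theirs, after some changed neighbours had been noticed.

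Among 67 families of the deposited Pfam and KEGG annotation with at least 8 kept members, 14 lay outside their random range, against 3.35 expected by chance. Some families share members and the random lists were drawn gene by gene, so the 14 are not separate results and the excess is not a test. The Ribosome family had a median log2 ratio of 0.49 above its range. All 12 members named as chloroplast proteins had ratios above 0, from 0.17 to 0.92, and the other 4 split, 2 above and 2 below 0. Peroxidases (median -1.01) and AP2 domain genes (-0.92) lay below, the latter sharing members with the ethylene list. WRI1 (Cs3g07310), a regulator of fatty acid synthesis, stood at RPKM 152 against 425, and all 9 fatty acid biosynthesis genes had ratios below 0, but their median of -0.71 lay inside its random range. These genes fall outside the naming rule and were chosen after their values were seen.

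The lower level of growth genes was weighed on the cell division, shoot meristem and cell wall loosening lists together. They hold 39 genes with a median of -0.87, of which 24 are wall genes. The authors called lower 11 of the 24 wall genes, 5 of the 8 meristem genes and 4 of the 7 division genes. Whether the choice of named genes shaped this pattern was not tested and stays open. Library scaling as the whole cause is argued against, since one factor moves every gene alike and the median of 15654 kept genes was 0.0024. Low read counts are argued against for wall genes only. The 16 members with RPKM of at least 5 had a median of -0.856, below -0.741, but 13 of them are wall genes, 3 are meristem genes and none is a cell division gene, so low counts stay open for those lists. A smaller share of growing buds in the light drought tissue remains open. The meristem and division lists gave -0.892, below the range from -0.772, which slower growth of the same tissue may give as well. Because the 2 explanations predict the same low medians, these values cannot tell them apart.

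The higher photosynthesis genes were weighed in the same way. Library scaling as the whole cause is argued against by the same median of all kept genes, 0.0024, against 0.58 for the 28 listed genes. The choice of named genes stays open. The authors called 10.7% of the list in this comparison, and how the other members entered the authors' deposited table is not given in the sources used here, so it may have favoured higher genes. An effect of light drought on chloroplast genes is a hypothesis beside a larger share of green tissue or another hour of collection, none of which was tested.

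Among kept genes in chromosome order, changed genes were neighbours more often than shuffling gives, with 23 pairs changed in the same direction against 2 to 12 in the central 95% of 10000 shuffles. The genes of a pair lay up to 49533 bases apart, and in some pairs the identifiers skip numbers between them. Other pairs lay close on the same strand, some of them 77, 102 and 258 bases apart. With no gene model between and identifiers at most 10 apart, 18 pairs remained, against 1 to 9 in the shuffles, which argues against the left-out genes as the cause. On chromosome 5, Cs5g34610 and Cs5g34620, both described as glycine-rich protein 23, and Cs5g34630 had ratios of -2.63, -3.40 and -3.60. Overlapping gene models are argued against as the cause of most pairs, since 8.70% of the pairs shared exon bases (exact binomial interval 1.07% to 28.0%). That count covers shared exon bases only, so close models without overlap were not tested. Near-identical neighbours stay open, since the same Pfam text was found for 11.1% of 9 annotated pairs (0.281% to 48.2%), too few to decide. Shared regulation of neighbours may also contribute and was not tested.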
